A study of Mus musculus with 4 samples.

How the data were processed

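Enhanced crosslinking and immunoprecipitation (eCLIP) maps where a protein touches RNA: cells are irradiated with ultraviolet light, the protein is pulled down with an antibody, and the crosslinked RNA fragments are sequenced beside an input library that skips the pull-down. The series holds 4 libraries of the mouse embryonic stem cell line J1, 2 input libraries and 2 libraries pulled down with an antibody to eIF4A3. Per the labels' protocols, the cells were grown without feeder cells in serum with leukemia inhibitory factor, irradiated with 400 mJ/cm2 at 254 nm, and sequenced as paired reads of 50 nt, and the 2 replicates per group were biological. The data used here are 1 peak list for the whole series. It gives each peak's chromosome, start, end, strand, log2 fold change and −log10 p-value, with no values per library and no gene names.

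The submitters' processing notes name cutadapt 1.18, STAR 2.6.1b and the mouse genome build mm9, without saying which did what. The peak caller, the test behind the p-values, the numerator and denominator of the fold change, and whether the replicates were pooled are not given in the sources used here. The log2 fold change of each peak is the authors' deposited value, and is the peak's own value with no spread over replicates. The −log10 p of each peak is likewise the authors' deposited value. The lowest log2 fold change was 2.00 and the lowest −log10 p was 5.01, while the numbers in the peak names ran up to 144404 for 30763 peaks present, so the deposited list is a filtered part of a longer numbering. Read totals are not in the list, so the depth behind each peak is unknown and no interval that needs it is given.

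Start and end were read as both belonging to the peak. In 6362 pairs on 1 strand the next peak starts at the position after the end of the one before it, no 2 peaks on the same strand overlap, and 128 peaks have the same start and end, which would have no length if the end were excluded. Whether positions count from 0 or from 1 is not stated, so each position is printed as in the list and may be off by 1. Positions are on mm9. The annotation at hand, GENCODE M21, is on GRCm38, and coordinates were not converted. As a check of the build, overlap with GRCm38 coding-transcript exons at the printed positions was 6.28% of peaks on the same strand and 2.94% on the opposite strand. On the same strand this varied by chromosome, from 0 of 12 peaks on Y and 0.67% on X to 37.7% on chromosome 16. Chromosome 16 had 374 of 993 peaks on the same strand and 0 on the opposite strand. No annotation was taken from these overlaps.

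The tests planned for feature classes, exon ends, genes with peaks, gene lists and single-exon genes all need an mm9 annotation and were not run. Peaks are named by position, under a rule fixed before the data were examined for a list without gene names: the 10 peaks with the highest fold change past a threshold of at least 8-fold (log2 of 3) with p at most 0.001, and the 5 clusters with the most peaks. Regions named under any other rule are marked as chosen after their values were seen.

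Peaks on the same chromosome and strand that lay within 10 kb of each other were joined into clusters, and peaks within 50 nt into sites. Clustering was compared with 100 random lists in which each peak kept its width and was moved to a uniform position within the span of its chromosome and strand. Relations across peaks are Spearman correlations with two-sided permutation tests of 100000 resamples, and the fold change on the 2 strands was compared by a two-sided permutation test of the difference in medians with as many resamples. The 3 p-values were adjusted by the Benjamini-Hochberg method. Because peaks of a cluster are not independent, 95% intervals come from redrawing whole clusters, with 300 draws for these relations, 2000 for the medians of trends along clusters and 1000 elsewhere. Shares have 95% Wilson intervals where stated. The alternatives fixed before the data were examined were other thresholds for the count of peaks and for the clusters, peaks merged within 50 nt, gaps of 5 and 50 kb, and strand ignored for the clusters. The closing section names those added afterwards. The functions were tested on simulated data: 500 of 500 planted clusters were recovered, and 5.0% of 200 unrelated pairs had a p-value under 0.05. The planted clusters lay far apart and the pairs held independent values. These runs therefore check the code, not how the tests behave on dependent peaks. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.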

Results

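The RNA targets of eIF4A3 were mapped in mouse embryonic stem cells. eIF4A3 is a DEAD-box RNA helicase and the RNA-clamping core of the exon junction complex, the protein assembly that splicing leaves on messenger RNA upstream of exon junctions. The study screened RNA helicases for a part in stem cell identity, and the 4 eCLIP libraries compared RNA pulled down with eIF4A3 with input RNA, with 2 libraries in each group. The peak list held 30763 peaks on 21 chromosomes, which were the autosomes, X and Y. Each peak carries 1 fold change and 1 p-value from the authors' calling, so the spread between replicates cannot be given for any of them. The read depth behind the peaks is unknown.

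The peaks were narrow, and most had a fold change below 8. The median fold change was 6.57 (log2 of 2.72), with quartiles of 5.17-fold and 8.80-fold, and the highest was 75.6-fold. Of all peaks, 9930 (32.3%) reached 8-fold with p at most 0.001, the stringent threshold here. At 16-fold with p at most 1e-05, 1122 peaks remained. The median −log10 p was 10.4, with quartiles of 7.24 and 16.1. The median width was 32 nt, with quartiles of 16 and 52 nt and a maximum of 249 nt. Many peaks adjoined another: 20.7% began at the position after the end of the peak before. Joining peaks within 50 nt on the same strand gave 22092 sites with a median width of 45 nt, of which 16003 (72.4%) were a single peak, and the most divided site held 12 peaks.

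**Figure D1:**
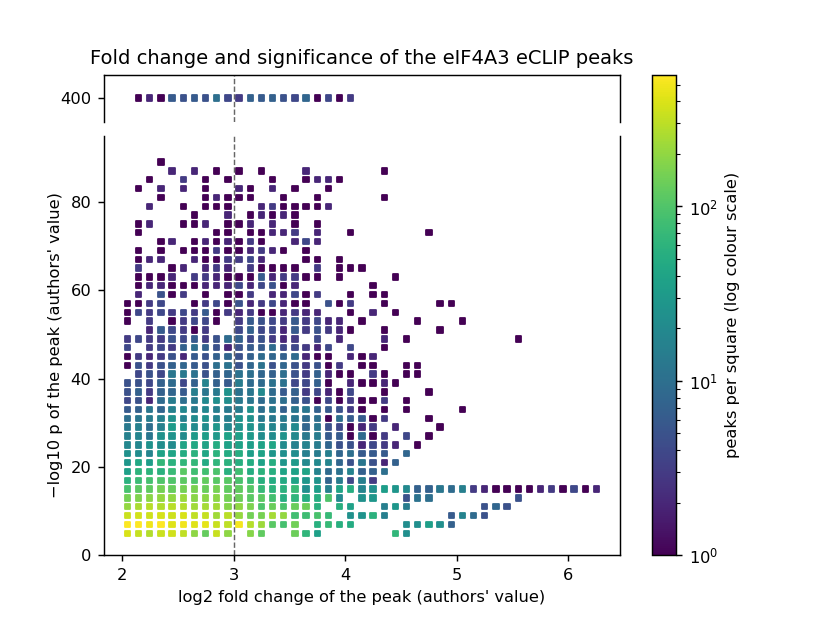
Each square counts the peaks in a step of log2 fold change (x axis) and of −log10 p (y axis, broken below 400), coloured by number on a log scale, and the dashed line marks a log2 fold change of 3. No peak lies between 88.1 and 400 in −log10 p, and a row of peaks at 15.7 runs out to the highest fold changes.

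The 10 peaks with the highest fold change past the threshold lay in 8 short stretches of 6 chromosomes and measured from 58.5-fold to 75.6-fold. The highest was a peak of 30 nt on the minus strand of chromosome 9, from 67192004 to 67192033 on mm9, with a fold change of 75.6. The 7 nt that follow it, from 67192034 to 67192040, formed a separate peak with a fold change of 67.6. Both belonged to a cluster of 32 peaks from 67166003 to 67223620. The peak in second place covered 66 nt on the plus strand of chromosome 7, from 35709461 to 35709526, at 74.6-fold, in a cluster of 5 peaks. The third, on the minus strand of chromosome 7 from 152458232 to 152458260, reached 69.6-fold. A peak of 9 nt on the minus strand of chromosome 10, from 127009612 to 127009620, reached 66.6-fold inside a cluster of 75 peaks. On chromosome 6, adjoining peaks from 120990401 to 120990411 and from 120990412 to 120990433 on the minus strand reached 58.5-fold and 65.6-fold, and a peak on the plus strand from 114623672 to 114623724 reached 64.5-fold. The remaining members of the 10 were a peak on the minus strand of chromosome 4, from 144728573 to 144728593, at 62.5-fold, and a peak on the plus strand of chromosome 5, from 73883208 to 73883266, at 59.5-fold. All 10 carried the same −log10 p of 15.7, so their p-values do not rank them. Once the offset given under the other observations is removed, all 10 fold changes lie close to whole numbers. Whole-number ratios would arise if the denominator were a single read. The read numbers behind these peaks are unknown, so neither the size nor the order of their fold changes need reflect binding. What the annotation places at these positions is not reported here, because the annotation at hand is on another build.

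The peaks with the highest listed −log10 p were other ones. The value of 15.7 shared by the 10 peaks above may be a limit of the reported p, so their true place is unknown. The value 400, the highest in the list, was given to 89 peaks in 36 clusters, and their fold changes did not exceed a log2 of 4.06. The clusters that held the most of these, chosen after their values were seen, were on the minus strand of chromosome 13 from 6599846 to 6624459, with 12 such peaks among 50, on the minus strand of chromosome 1 from 71672611 to 71699651, with 10 among 54, and on the plus strand of chromosome 2 from 130100370 to 130102593, with 10 among 23. Across all peaks, fold change and −log10 p rose together only weakly, with a Spearman rho of 0.208 (95% interval 0.180 to 0.235, permutation test, adjusted p = 1.5e-05). Higher fold changes went with narrower peaks, with a rho of -0.140 (95% interval -0.156 to -0.123, permutation test, adjusted p = 1.5e-05). Both adjusted p-values rest on the smallest p that the permutations can give. The permutations shuffle single peaks freely, so they ignore likeness within clusters and the lower limits of the list in fold change and p. Those limits alone could tie fold change to width or to p, so neither relation is shown to hold beyond the list. Over the 22092 sites, rho with width was -0.066 with the mean fold change of each site and 0.024 with the highest fold change of each site.

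Peaks were gathered into clusters far more than uniform placement gives. Joining peaks within 10 kb on the same strand gave 6570 clusters, against a median of 28620 clusters (range 28515 to 28729) in 100 random lists (one-sided permutation p = 0.0099, the smallest that 100 lists can give). Of all peaks, 78.6% followed another within 10 kb on the same chromosome and strand, against 6.97% in the random lists. The median distance between neighbouring peaks was 784 nt, against 100486 nt. Single peaks made up 2655 of the clusters (40.4%). At the other end, 796 clusters with at least 10 peaks held 16392 peaks, 53.3% of the list. Clusters of 2 or more peaks had a median span of 4640 nt. The random lists ignore that transcripts cover only part of the genome, so the comparison measures gathering of any kind.

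The 5 clusters with the most peaks lay on chromosomes X, 4, 5 and 1 and held 634 peaks, 2.06% of the list. The largest covered 97324 nt on the plus strand of chromosome X, from 148269778 to 148367101, with 152 peaks in 79 sites, a median fold change of 6.22 and a highest of 19.0. The next, on the plus strand of chromosome 4 from 32744143 to 32860295, held 126 peaks in 79 sites with a median of 7.80-fold. The cluster on the plus strand of chromosome 5, from 116009553 to 116072041, held 124 peaks in 55 sites, and its median of 12.0-fold was the highest of the 5, with 100 of the 124 peaks (80.6%) past the threshold. The cluster on the minus strand of chromosome 4, from 144647422 to 144780417, was the longest at 132996 nt, with 118 peaks in 62 sites, a median of 9.79-fold and 72.0% past the threshold. The cluster on the plus strand of chromosome 1, from 34209140 to 34286033, held 114 peaks in 61 sites with a median of 6.52-fold and 27.2% past the threshold, as against 23.7% on chromosome X and 44.4% in the first chromosome 4 cluster. Sites in these 5 clusters had median widths of 45 to 69 nt and were separated by median distances of 508 to 1378 nt. A further cluster, chosen after its values were seen, had 80 of its 84 peaks past the threshold, on the minus strand of chromosome 2 from 179911702 to 179943034.

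**Figure D2:**
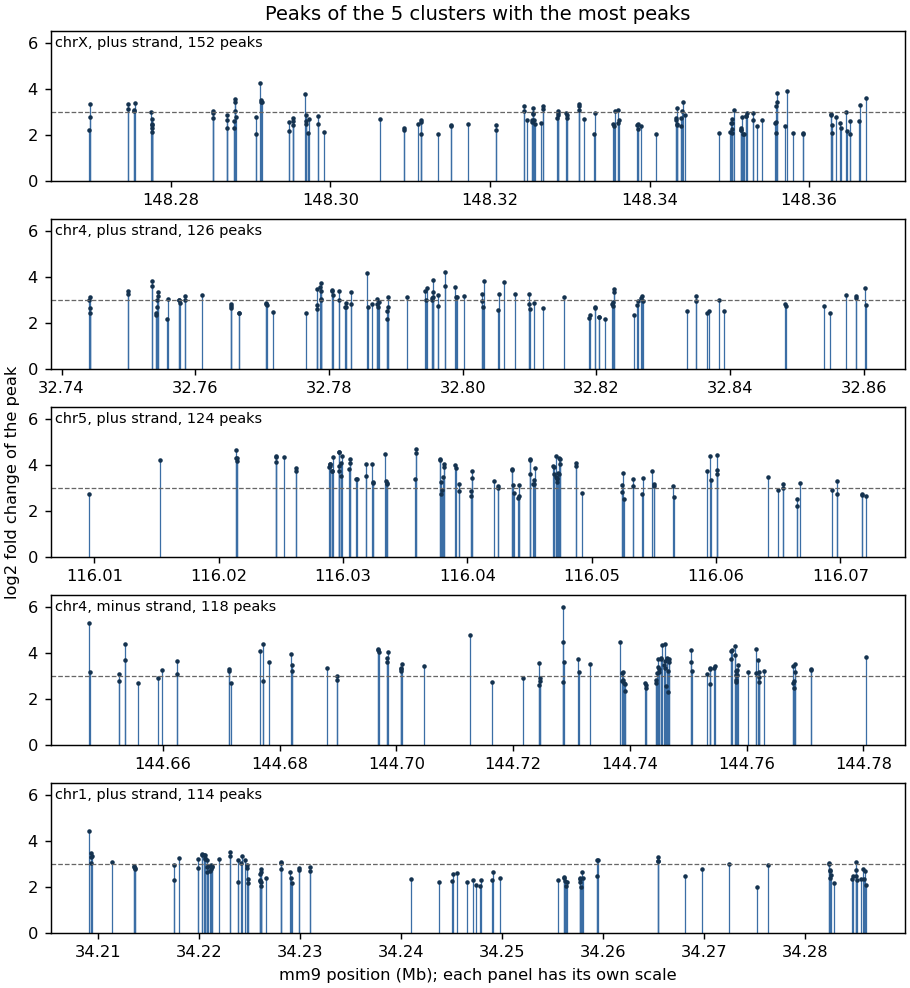
Each panel shows 1 of the 5 clusters with the most peaks, with mm9 position in Mb on the x axis and the log2 fold change of each peak (authors' value) on the y axis. The dashed line marks a log2 fold change of 3. In the chromosome 5 cluster 100 of 124 peaks lie on or above the line, and in the chromosome X cluster 36 of 152.

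Within clusters, neighbouring sites were separated by a median of 1079 nt, with quartiles of 261 and 2890 nt, over 15522 distances. At short range the distances between peaks did not fall off evenly. There were 705 distances of 40 to 59 nt, 598 of 60 to 79 nt, 777 of 80 to 99 nt and 525 of 100 to 119 nt. The ratio of the 80 to 99 nt class to the 60 to 79 nt class was 1.30 (95% interval 1.17 to 1.46 from redrawing clusters). The classes were chosen after the distances had been seen, so the interval describes this rise and is not an independent test of it. The ratio was 1.22 on the plus strand, 1.39 on the minus strand and 1.72 among peaks past the threshold.

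**Figure D3:**
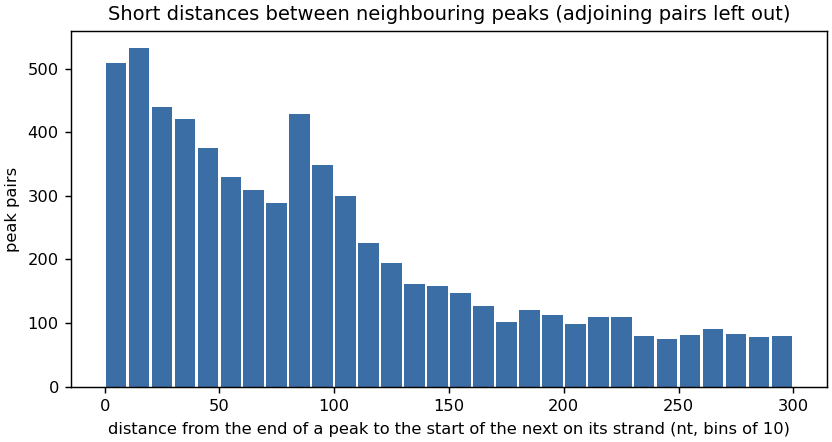
Bars count pairs of neighbouring peaks on 1 strand by the distance between them, in nt, in bins of 10 nt, with the 6362 adjoining pairs left out. The count falls to 289 pairs at 70 to 79 nt and stands at 429 pairs at 80 to 89 nt.

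No position carried peaks on both strands. No peak on the plus strand overlapped a peak on the minus strand, and 54 of the 16298 plus-strand peaks (0.331%) had a minus-strand peak within 1000 nt. The plus strand carried 53.0% of peaks (95% interval 50.5 to 55.4% from redrawing clusters) and 51.9% of clusters (Wilson 95% interval 50.7 to 53.1%). The median log2 fold change was 2.71 on the plus strand and 2.73 on the minus strand. The difference of -0.016 (95% interval -0.059 to 0.016) was not significant (permutation test, adjusted p = 0.085).

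Chromosome 11 held the most peaks, 2928 in 569 clusters, followed by chromosome 2 with 2523 and chromosome 4 with 2311. Chromosome Y held 12 peaks in 3 clusters. Chromosome X held 895 peaks in 143 clusters, and at 6.26 peaks per cluster it was the highest of all chromosomes. With the largest cluster of every chromosome left out, the value for X was 5.23 and stayed the highest, beside 5.20 on chromosome 15. On chromosome X, 65.3% of peaks were on the plus strand, and 152 of those 584 peaks came from its largest cluster. The median log2 fold change per chromosome ranged from 2.61 on chromosome 13 to 2.82 on chromosomes 4 and 12, leaving out Y. The share of peaks past the threshold ranged, again leaving out Y, from 26.8% on chromosome 8 to 40.6% on chromosome 4. With 1 peak list and no replicate values, differences between chromosomes were not tested.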

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

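Several of these settings were chosen after the data were seen: merging only adjoining peaks, sites in place of peaks (with the highest or the mean fold change), leaving out tied p-values, only peaks past the threshold for the relations of fold change, strand permuted by cluster, the classes of short distances, and the trends along clusters with all their settings. No paired analysis was possible because the peak list gives no values per replicate, and for the same reason no replicate could be left out. The alternatives for feature classes, exon ends, genes and gene lists were not run, since no mm9 annotation was at hand. The number of peaks past the threshold followed the threshold: 9930 at 8-fold, 30763 at 4-fold with p at most 0.001, which is the whole list, and 1122 at 16-fold with p at most 1e-05. The number of clusters was 6570 at 10 kb, 8520 at 5 kb, 3845 at 50 kb, 3590 from peaks past the threshold alone (fewer peaks by construction) and 6412 with strand ignored. In each of these settings it lay below all 100 random lists. Merging moved the number of peaks from 30763 to 22092 (within 50 nt) or 24401 (adjoining only), and the median width from 32 to 45 or 42 nt, and no peak lay outside the named chromosomes. The relation of fold change with width turned. Its rho was -0.140 over peaks and -0.058 among peaks past the threshold. Over sites it was 0.024 with the highest fold change of their peaks and -0.066 with the mean fold change. The turn therefore came with taking the maximum. The relation of fold change with −log10 p stayed above 0 and past its threshold throughout, from 0.054 among peaks past the threshold to 0.231 over sites. The strand difference in fold change stayed short of the threshold in all settings, though its sign turned from -0.016 to 0.0034 among peaks past the threshold, and a permutation test that moved strand by cluster gave p = 0.43. The trend of log2 fold change along clusters, at a median rho of -0.054, was -0.032 without the first and last peak (sign-flip permutation p = 0.051) and 0.018 among peaks past the threshold (p = 0.65). The cause was not tested. Depth limits every value here in a way that cannot be measured, since no read totals are given.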

Other observations

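All tests in this part were chosen after the values they concern had been seen. Peaks in the same cluster resembled each other: clusters accounted for an intraclass correlation of 0.289 in log2 fold change over 28108 peaks in 3915 clusters, against at most 0.013 in 1000 shuffles (permutation p = 0.001, the smallest they can give). Over sites, where adjoining peaks count once, it was 0.256. Within the 796 clusters of at least 10 peaks, −log10 p fell in the 5′ to 3′ direction of the strand given in the list. The median Spearman rho between position and −log10 p was -0.160 (95% interval -0.186 to -0.123), and rho was below 0 in 534 clusters (67.1%). A two-sided sign-flip permutation test of the mean rho gave p = 1e-05, the smallest it can give. In 5 bins of the order along the cluster, the median −log10 p was 14.3, 13.8, 13.5, 13.1 and 11.7. The fall of −log10 p was seen on both strands (median rho -0.154 on plus and -0.169 on minus), so it follows the strand and not the chromosome's own direction. Among peaks past the threshold alone the fall was smaller, with a median rho of -0.068 (95% interval -0.127 to -0.009) over 148 clusters. The direction assumes that the strand in the list is that of the bound RNA, which no source states. Log2 fold change moved much less, with a median rho of -0.054 and medians of 2.76, 2.79, 2.80, 2.77 and 2.68.

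Peak width could produce the fall of −log10 p, since wider peaks gather more reads, but with width held fixed the median rho was -0.154. Neighbouring genes joined in one cluster could also produce it. With clusters made at a 5 kb gap the median rho was -0.109, smaller but still below 0 beyond its interval (-0.147 to -0.078). A 5 kb gap can still join neighbouring genes, so this explanation stays open. End peaks alone were not the whole of the fall, as the median rho was -0.124 without the first and last peak. Uneven coverage of the transcripts also stays open, because the list gives no read numbers. It may be tracked more closely by −log10 p than by fold change.

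The excess of distances between peaks just above 80 nt may mark introns between bound exons. The mode of these distances between 60 and 150 nt was 82 nt (95% interval 82 to 88 nt from redrawing clusters), and the mode of 209529 introns of coding transcripts, taken as lengths from GENCODE M21 with no use of positions, was 87 nt. The length of 2 full reads, 100 nt, lies outside the interval, which ends at 88 nt. The lengths of the reads as mapped are not given, so a pair of shortened reads is not excluded. Introns of 80 to 99 nt outnumbered those of 60 to 79 nt by 3.67 times and for the peak distances the figure was 1.30 times, so introns could account for only part of the short distances. The test compares lengths only and does not show that any named pair of peaks flanks an intron. A distance equals an intron length only if both peaks reach the edges of their exons. Binding sites that lie away from the edges would be farther apart. Where peaks lie within exons was not checked, since no mm9 annotation was at hand.

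The p-values hold 2 ties that bear on any ranking. A −log10 p of 15.6576 was given to 156 peaks on 18 chromosomes, all with a log2 fold change of at least 4.10, and 400 to 89 peaks, with 88.1 the next value below. The tied value equals −log10 of 2.2e-16 to 4 decimals, which suggests a limit of the reported p in statistical software for these peaks. It is no limit of the whole list, since 8055 peaks (26.2%) lay above it, 210 of them with a log2 fold change of at least 4.10. Exactly the same set of reads listed more than once would give equal fold changes, and the 156 peaks had 76 distinct ones. Exact repeats therefore cannot explain the whole tie, but the count does not decide for the peaks that share a fold change. It also does not decide for neighbouring peaks that share only some of their reads. Of the 94 peaks with a log2 fold change of at least 5, 56 were below the tied value, 35 at it and 3 above it, so p does not rank those 35 among themselves.

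The fold changes were also stepped. The list holds 3486 distinct log2 fold changes, and the most frequent, 2.597, was given to 468 peaks. After subtracting an offset of 0.0123 from the log2 fold change, chosen as the best fit, 12.6% of peaks were whole-number ratios within 0.002. With each distinct fold change moved at random by up to 0.05, the best offset gave at most 3.56% in 20 such lists. Counted against the coding genes of GRCm38, chromosome X had 15.1 clusters per 100 genes, the lowest of 20 chromosomes leaving out Y, where the next were chromosome 6 with 22.0 and chromosome 7 with 22.2. Per 1000 introns of coding transcripts it was also the lowest in clusters, with 19.2 beside 23.6 on chromosome 6. Counted in peaks it was not the lowest: it had 94.4 peaks per 100 genes and 120 per 1000 introns, while chromosome 3 had 91.7 and 96.3. Chromosome 8 was the highest by all 4 counts, with 40.4 clusters per 100 genes and 214 peaks per 1000 introns. All 4 counts were set against every annotated coding gene or intron, whether expressed in these cells or not. Expression is not in the list, so the counts do not separate binding from the number of expressed genes.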
